A study of Mus musculus with 10 samples.

How the data were processed

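Poly(A) RNA of gastrocnemius muscle from wild-type mice was sequenced as paired-end libraries on an Illumina NovaSeq, per the labels' protocols, in 5 Sham and 5 HLI samples. The tissue is taken from the sample labels. The descriptions disagree on its handling: the series text speaks of cells and names another RNA reagent and another sequencing company than the sample protocol, which itself mentions adipose material, so the extraction protocol is uncertain. Groups and replicate numbers were taken from the sample labels. The submitters' processing notes name HISAT2 2.0, Bowtie 0.12.2 and the genome build mm8, without saying what each was used for. The counting tool, the gene annotation and the use of strand are not given in the sources used here, so overlapping and antisense genes, and near-identical copies such as globin genes, cannot be told apart by these values. The reference annotation at hand is of another build, and no coordinates are given for that reason.

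The authors deposited 1 table with 21956 genes, their Ensembl identifiers and symbols, and for each sample an estimated count and a TPM value, per the file headers. The deposited estimated counts are not normalized, and 93.4% of them are whole numbers. The deposited TPM values, named so per the file headers and by definition relative to gene length, sum to 1000000 in each sample. Totals of the estimated counts ran from 16556385 to 22136299, 4526 genes were at 0 in every library, and 83 genes had no symbol. All per-sample columns were used. No library was left out, and no pair of libraries held the same values.

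Estimated counts were rounded to whole numbers and tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16. Libraries were scaled by TMM, genes were kept by filterByExpr with a count minimum of 10 and a total minimum of 15, which left 13404 genes, and HLI was compared with Sham with no covariate. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Levels are CPM with TMM-scaled library sizes, as mean ± SD over 5 samples. Standard errors and adjusted p-values of single genes are those of the edgeR fit unless another tool is named.

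For the lists, 26 sets of genes were fixed before the data were examined, for pathways of hypoxia, angiogenesis, inflammation, regeneration and metabolism and for the cell types that muscle can hold. Log2 CPM with a prior count of 2 was tested with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01 and adjustment over the 26 lists, and then with an estimated correlation. A list's score in a library is the mean over its members of the log2 CPM relative to the mean of the 10 libraries. The mean log2 difference of a list is the difference of its scores between groups, with the standard error from the scores. Exact two-sided permutation tests of Fgf13 and of list scores used the 252 assignments of 10 samples to 2 groups of 5, with a smallest possible p of 0.0079. The other lists, tested in the same way, were fibro-adipogenic progenitor markers, Schwann cell and nerve markers, muscle atrophy and proteolysis, and oxidative, heat and unfolded-protein stress.

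The rule for named genes, fixed before the data were examined, took the called genes with the largest fold changes (0 genes), the called members of each list (0 genes) and 9 fixed genes, namely Fgf13, Hif1a, Epas1, Vhl, Egln1, Egln3, Vegfa, Kdr and Pecam1. The other named genes were chosen after the values were seen. They are the 5 higher and 5 lower genes with the smallest unadjusted p at a mean of at least 10 CPM in the higher group, the 2 members of each list with the smallest unadjusted p under 0.05 at a mean of at least 1 CPM, and Myh3, Myh8 and Myl4. A few further list members and genes called by DESeq2 are given beside them.

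The edgeR and camera steps were tested on simulated counts for the 13404 genes, with the means and library sizes of these samples. Each gene was drawn independently of the others, so shared shifts of genes between libraries were not simulated. Of 100 genes changed 2-fold and 100 changed 4-fold, 63% and 95% were recovered, 5.85% of the calls were false, and a planted list had an adjusted p of 2.5e-15. The estimated biological coefficient of variation of the real samples was 0.252.

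Alternatives were the replicate number as a block, leaving out each library, no filter on low counts, DESeq2's size factors in edgeR, DESeq2 1.42.0 itself, a robust prior in edgeR, a fold-change threshold, and for the lists an estimated correlation, quantile normalization and no filter. Planned fits to FPKM could not be run because the deposited normalized values are TPM. In their place limma-trend was run on log2(TPM + 1) and log2(TPM + 0.1), on quantile-normalized values and on values scaled by median of ratios, and these fits, the permutation tests of list scores and the rotation test fry were chosen after seeing the data.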

Results

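Poly(A) RNA from the gastrocnemius, a large calf muscle, of wild-type mice was sequenced in 10 samples, 5 labelled Sham and 5 labelled HLI. HLI is taken here as hindlimb ischaemia, which the labels do not spell out, and no time point is given. The deposited estimated counts summed to between 16556385 and 22136299 per sample, and 13404 of the 21956 listed genes passed the filter on low counts. Nothing in the labels says that the samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. The series title concerns endothelial FGF13, angiogenesis and the degradation of HIF-1α. The comparison of HLI with Sham asks which transcripts differ in muscle between these conditions, Fgf13 among them.

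Fgf13 (ENSMUSG00000031137), which encodes a fibroblast growth factor homologous factor that is not secreted, stood at 28.4 ± 2.88 CPM (counts per 1000000 counts of the library; SD, n = 5) in Sham and at 24.7 ± 8.42 CPM (SD, n = 5) in HLI. The log2 fold change of HLI over Sham was -0.20 (SE 0.19), smaller than the spread between samples (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.54, and exact two-sided permutation p = 0.254). HLI replicates 1, 2, 3 and 5 lay between 17.6 and 22.3 CPM, below the range of 25.2 to 31.6 CPM in Sham, whereas HLI replicate 4 lay above it at 39.3 CPM. Without HLI replicate 4 the log2 fold change was -0.44 (edgeR unadjusted p = 0.0031, adjusted p = 0.081). Without HLI replicate 3 it was -0.10. On the deposited TPM without further scaling, where the median of all genes was 0.19, it was -0.0036, and on TPM scaled by median of ratios -0.20. Of 17 measured members of the FGF family list, 0 passed the test, also when adjusted over the list alone, and the mean log2 difference of the list was -0.06 (SE 0.05, camera adjusted p = 0.53). That mean was -0.03 without Sham replicate 2, 0.02 without the filter on low counts, -0.19 after quantile normalization, and 0.08 on unscaled TPM, or -0.10 relative to the median of all genes.

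Among genes of oxygen sensing, Hif1a (ENSMUSG00000021109), which encodes the regulated HIF-1α subunit, had 59.2 ± 27.2 CPM in Sham and 82.5 ± 24.6 CPM in HLI (SD, n = 5), a log2 fold change of 0.48 (SE 0.28, edgeR adjusted p = 0.36). It was 0.78 without Sham replicate 3 (adjusted p = 0.25) and 0.30 without HLI replicate 3 (adjusted p = 0.69). Epas1, which encodes HIF-2α, had 305 ± 29.3 CPM in Sham and 255 ± 45.8 CPM in HLI. Vhl, the substrate receptor of the ubiquitin ligase for HIF-α, had a log2 fold change of 0.19 (SE 0.13). The prolyl hydroxylase genes Egln1 and Egln3 had log2 fold changes of -0.40 (SE 0.18) and -0.41 (SE 0.20), which were -0.26 and -0.28 without HLI replicate 3. The adjusted p of Epas1, Vhl, Egln1 and Egln3 lay between 0.29 and 0.40, so none of them passed the edgeR test. The list of HIF-1 target genes was lower in HLI by camera with a preset correlation, with a mean log2 difference of -0.19 (SE 0.12, adjusted p = 0.0063), and 18 of its 24 measured members had values below 0. The call was not kept with an estimated correlation (adjusted p = 0.48). On unscaled TPM the mean difference was 0.0023, or -0.18 relative to the median of all genes. The score of this list, the mean log2 CPM of its members relative to all libraries, was -0.54 in HLI replicate 3 and between -0.09 and 0.07 in the other HLI libraries, against 0.03 to 0.14 in Sham. Without HLI replicate 3 the mean was -0.08 (adjusted p = 0.031). Pfkfb3, which encodes an activator of glycolysis, had 318 ± 71.2 CPM in Sham and 194 ± 63.3 CPM in HLI, and Mxi1, a MYC antagonist, had 52.6 ± 5.10 and 43.1 ± 3.64 CPM. In the other direction Ddit4 had 8.11 ± 1.06 and 15.1 ± 8.75 CPM (edgeR adjusted p = 0.29). The list holds glycolysis genes such as Ldha, Pgk1 and Hk2. HLI replicate 3 was also the lowest library for the fast fibre and glycolysis lists, at -1.03 and -1.02. Whether the lower HIF-1 targets reflect a lower share of muscle fibre RNA was not tested. The list of HIF subunits and HIF-α turnover had a mean log2 difference of -0.09 (SE 0.05, camera adjusted p = 0.037, and adjusted p = 0.48 with an estimated correlation), and of 0.12 on unscaled TPM, or -0.07 relative to the median of all genes. Its adjusted p was 0.066 without Sham replicate 3, 0.064 without Sham replicate 4, 0.051 without HLI replicate 1, 0.055 without HLI replicate 3 and 0.067 without HLI replicate 5.

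Endothelial transcripts did not pass the test as single genes, nor as a list in the planned fit. Pecam1, an endothelial adhesion molecule, had 305 ± 64.4 CPM in Sham and 334 ± 54.4 CPM in HLI (SD, n = 5). Kdr, the main VEGF receptor gene, had 224 ± 51.2 and 213 ± 50.2 CPM, with a log2 fold change of -0.08 (SE 0.20, edgeR adjusted p = 0.84) that was 0.12 on unscaled TPM, -0.08 on TPM scaled by median of ratios, 0.05 without Sham replicate 1, 0.0094 without HLI replicate 1 and 0.0032 without HLI replicate 3. Vegfa had 104 ± 12.1 and 92.4 ± 33.5 CPM, with a log2 fold change of -0.17 (SE 0.23, adjusted p = 0.67) that was 0.00042 on unscaled TPM, -0.20 on TPM scaled by median of ratios, -0.0088 without HLI replicate 3 and -0.36 without HLI replicate 4. The 24 endothelial markers had a mean log2 difference of 0.08 (SE 0.13, camera adjusted p = 0.39, and 0.034 after quantile normalization, and 0.79 with an estimated correlation). Their mean lay between 0.02 without HLI replicate 5 and 0.16 without Sham replicate 1. The 14 pericyte and smooth muscle markers had a mean of -0.06 (SE 0.07, camera adjusted p = 0.40), from -0.11 without Sham replicate 4 to -0.01 without Sham replicate 2, and of 0.14 on unscaled TPM, or -0.05 relative to the median of all genes. The 29 angiogenic ligands and receptors had a mean of 0.26 (SE 0.13, camera adjusted p = 0.069, and adjusted p = 0.59 with an estimated correlation). With the preset correlation this list passed the threshold without Sham replicate 1 (adjusted p = 0.0068), without Sham replicate 2 (adjusted p = 0.048), without HLI replicate 1 (adjusted p = 0.015) and after quantile normalization (adjusted p = 0.021). Within it, Apln, which encodes an endothelial tip cell peptide, had 13.3 ± 5.93 CPM in Sham and 24.9 ± 6.42 CPM in HLI, and Cxcr4, a chemokine receptor, had 12.0 ± 9.96 and 29.3 ± 8.34 CPM. In both of these genes Sham replicate 1 was the highest Sham library, at 23.6 and 29.4 CPM. Of the 29 members, 20 had values above 0 and 9 below. Cxcl12, which encodes the ligand of CXCR4, was lower in HLI, with 322 ± 41.2 and 224 ± 56.3 CPM. Flt1, a VEGF receptor gene, had 167 ± 14.2 and 124 ± 26.8 CPM, and every HLI library lay below every Sham library. Neither passed the edgeR test (adjusted p = 0.29 for each).

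Cell cycle genes were higher in HLI as a group by camera with a preset correlation. Their mean log2 difference was 1.23 (SE 0.46, camera adjusted p = 6.9e-09, and adjusted p = 0.48 with an estimated correlation), and 18 of 18 measured members had values above 0. The score was 1.55 in HLI replicate 1 and 1.51 in HLI replicate 3, whereas HLI replicates 2 and 4, at -0.22 and -0.13, lay within the Sham range of -1.30 to 0.01. Of the members, 0 passed the edgeR test over all genes and 16 passed when adjusted over the list alone, a count that was 7 without HLI replicate 1. The exact two-sided permutation p of the list's score was 0.040 (0.17 after adjustment over 26 lists). Cdk1, the kinase that drives entry into mitosis, had 3.59 ± 1.47 CPM in Sham and 12.1 ± 6.72 CPM in HLI (SD, n = 5), a log2 fold change of 1.75 (SE 0.39). Cenpf, a kinetochore protein gene, had 2.62 ± 0.67 and 9.51 ± 6.90 CPM. In both genes every HLI library lay above every Sham library.

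**Figure D1:**
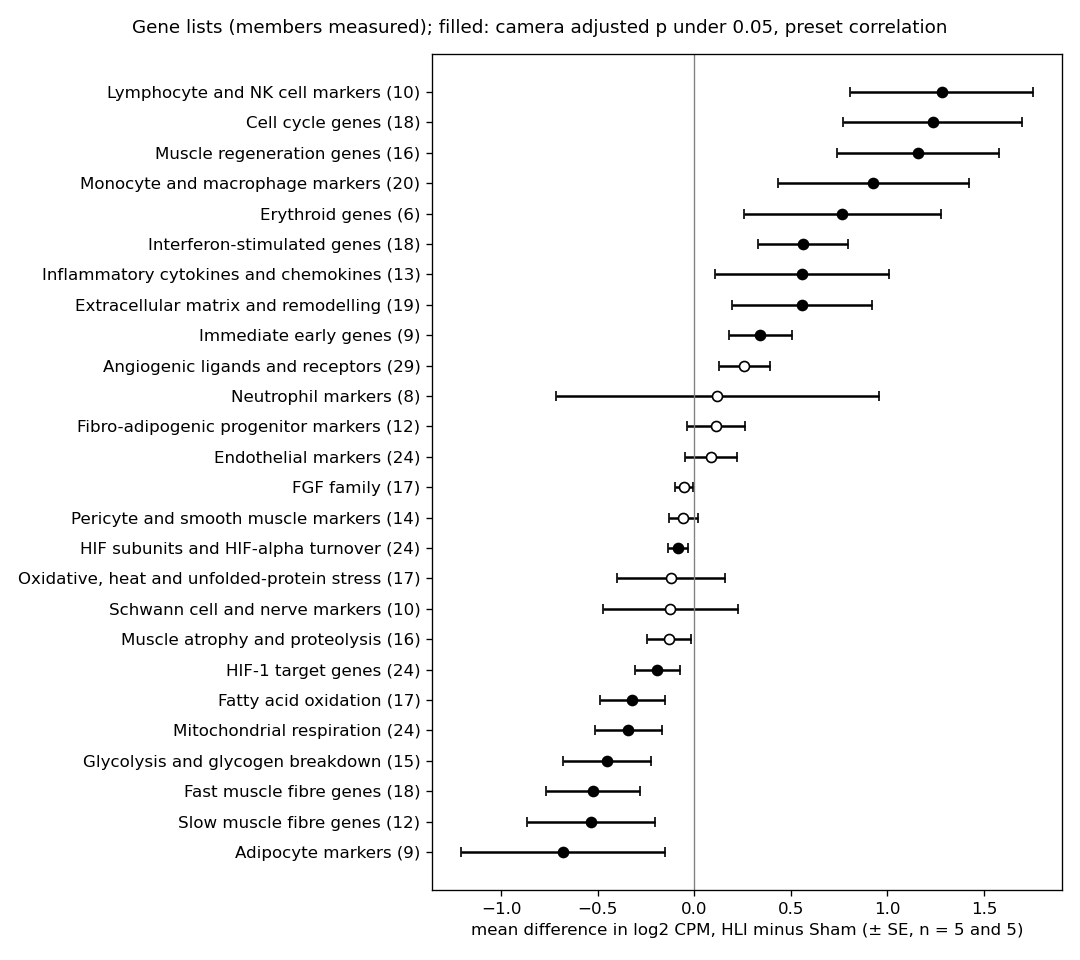
Mean difference in log2 CPM between HLI and Sham for each of 26 gene lists, with the number of measured members in parentheses; points are means, bars are standard errors over 5 and 5 libraries, and filled points mark an adjusted p under 0.05 by camera with a preset correlation. Of the 17 filled lists, 9 lie above 0 and 8 below 0, and with an estimated correlation 0 lists pass.

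Immune cell transcripts other than neutrophil markers were also higher as groups by camera with a preset correlation. The 20 monocyte and macrophage markers had a mean log2 difference of 0.93 (SE 0.49, camera adjusted p = 8.6e-06, and adjusted p = 0.48 with an estimated correlation), and 20 of 20 had values above 0, although 0 passed the edgeR test, also when adjusted over the list alone. The exact two-sided permutation p of their score was 0.11. The score was 1.44 in HLI replicate 1 and 1.11 in HLI replicate 3, and HLI replicates 2 and 4, at 0.06 and -0.74, lay within the Sham range of -1.24 to 0.34. Mpeg1, a macrophage pore-forming protein gene, had 70.1 ± 56.0 CPM in Sham and 241 ± 172 CPM in HLI, and Gpnmb, a gene of phagocytic macrophages, had 18.6 ± 7.01 and 76.6 ± 82.8 CPM, with 222 CPM in HLI replicate 3. The 10 measured lymphocyte and NK cell markers had a mean of 1.28 (SE 0.47, camera adjusted p = 7.6e-05, and adjusted p = 0.48 with an estimated correlation). Of these, 5 passed when adjusted over the list alone. That count was 9 without Sham replicate 1, and 0 without any 1 of Sham replicates 2 to 5 or HLI replicates 3 and 5. The T cell kinase gene Lck had 0.47 ± 0.37 CPM in Sham and 1.81 ± 1.29 CPM in HLI. The 18 interferon-stimulated genes had a mean of 0.56 (SE 0.23, camera adjusted p = 6.3e-06, and adjusted p = 0.48 with an estimated correlation), with 18 of 18 above 0; Zbp1, a nucleic acid sensor, had 2.77 ± 1.19 and 6.14 ± 2.19 CPM. The 13 measured cytokines and chemokines had a mean of 0.56 (SE 0.45, camera adjusted p = 0.037, and adjusted p = 0.55 with an estimated correlation), and 3 passed when adjusted over the list alone. Ccl8, a monocyte-attracting chemokine gene, had 4.41 ± 2.52 CPM in Sham and 13.7 ± 6.95 CPM in HLI. The cytokine list's mean was 0.85 without Sham replicate 3 and 0.29 without HLI replicate 1, and its adjusted p was 0.37 without HLI replicate 1, 0.051 without Sham replicate 1, 0.067 without Sham replicate 4 and 0.079 without Sham replicate 5. Its count over the list alone was 0 without Sham replicates 2, 4 or 5 or HLI replicates 3 or 5, and 1 without HLI replicate 1. The 8 measured neutrophil markers had a mean of 0.12 and a median of -0.15 (SE of the mean 0.84, camera adjusted p = 0.94). Their score was 1.97 in Sham replicate 3 and 2.18 in HLI replicate 1, and between -1.53 and 0.55 in the other libraries.

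Genes of muscle regeneration were higher as a group by camera with a preset correlation. Their mean log2 difference was 1.16 (SE 0.42, camera adjusted p = 0.00096, and adjusted p = 0.48 with an estimated correlation). Of 16 measured members, 6 passed when adjusted over the list alone and 0 over all genes. The count was 0 without Sham replicate 2, without Sham replicate 4 or without HLI replicate 3. Myog, which encodes a regulator of myoblast differentiation, had 8.62 ± 2.61 CPM in Sham and 26.1 ± 22.8 CPM in HLI, and Myf5, a gene of activated muscle stem cells, had 1.53 ± 0.26 and 3.67 ± 2.05 CPM. The embryonic and neonatal myosin heavy chain genes Myh3 and Myh8, made in newly formed fibres, did not divide the libraries by group. Myh3 stood at 164 CPM in Sham replicate 1 and between 3.97 and 5.63 CPM in the other Sham libraries. It stood at 7.71 CPM in HLI replicate 1 and between 79.9 and 442 CPM in the other HLI libraries. Myh8 stood at 78.2 CPM in Sham replicate 1, at 1.65 CPM in HLI replicate 1 and at 695 CPM in HLI replicate 3. The log2 fold changes of Myh3 and Myh8 were 2.13 (SE 1.20, edgeR adjusted p = 0.34) and 3.49 (SE 1.45, adjusted p = 0.29).

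**Figure D2:**
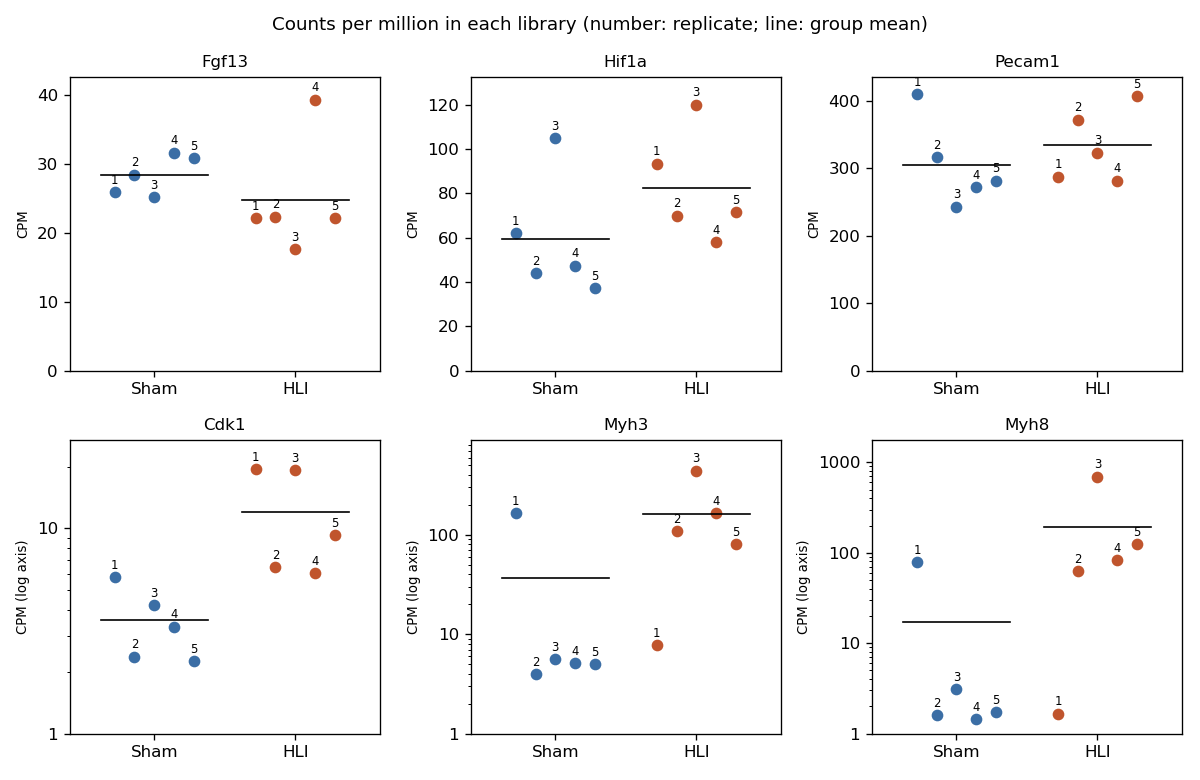
CPM of 6 genes in each of the 10 libraries; each point is a library marked with its replicate number, the line is the group mean, and the lower 3 axes are logarithmic. Fgf13 lies at 39.3 CPM in HLI replicate 4, and Myh3 lies at 164 CPM in Sham replicate 1 and at 7.71 CPM in HLI replicate 1.

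Genes of mature muscle fibres and of their energy metabolism were lower in HLI as groups by camera with a preset correlation. The 18 fast fibre genes had a mean log2 difference of -0.53 (SE 0.24, camera adjusted p = 1.7e-07) with 17 below 0, and the 12 slow fibre genes had a mean of -0.53 (SE 0.33, camera adjusted p = 0.0028) with 10 below 0. With an estimated correlation neither passed (adjusted p = 0.48 for each). Myoz1, a fast fibre Z-disc protein gene, had 1385 ± 259 CPM in Sham and 910 ± 278 CPM in HLI, and Myl3, a slow fibre myosin light chain gene, had 513 ± 176 and 246 ± 120 CPM, with 38.5 CPM in HLI replicate 3. The 15 genes of glycolysis and glycogen breakdown had a mean of -0.45 (SE 0.23, camera adjusted p = 3.2e-06, and adjusted p = 0.48 with an estimated correlation). The 24 genes of mitochondrial respiration had a mean of -0.34 (SE 0.17, camera adjusted p = 1.7e-07), and the 17 of fatty acid oxidation a mean of -0.32 (SE 0.17, camera adjusted p = 1.6e-05). With an estimated correlation neither passed (adjusted p = 0.48). On unscaled TPM, where the median of all genes was 0.19, the mean was -0.32 for fast and for slow fibre genes, -0.25 for glycolysis, -0.14 for respiration and -0.12 for fatty acid oxidation. After quantile normalization it was -0.25 for fast fibre genes and -0.29 for glycolysis. All measured members of these 3 metabolic lists had values below 0. Phka1, a phosphorylase kinase subunit gene, had 853 ± 161 CPM in Sham and 589 ± 185 CPM in HLI, and Cox6a2, a muscle subunit gene of cytochrome c oxidase, had 512 ± 128 and 328 ± 114 CPM. Over the lists alone 0 genes passed in any of these 5 lists. HLI replicate 3 had the lowest score in each of them, at -1.03 for fast fibre genes. Without it the means were -0.33 for fast and -0.27 for slow fibre genes, -0.25 for glycolysis and -0.21 for respiration, and all 4 calls with a preset correlation held. HLI replicates 2 and 4 lay within the Sham range for fast fibre genes, at 0.02 and 0.31.

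**Figure D3:**
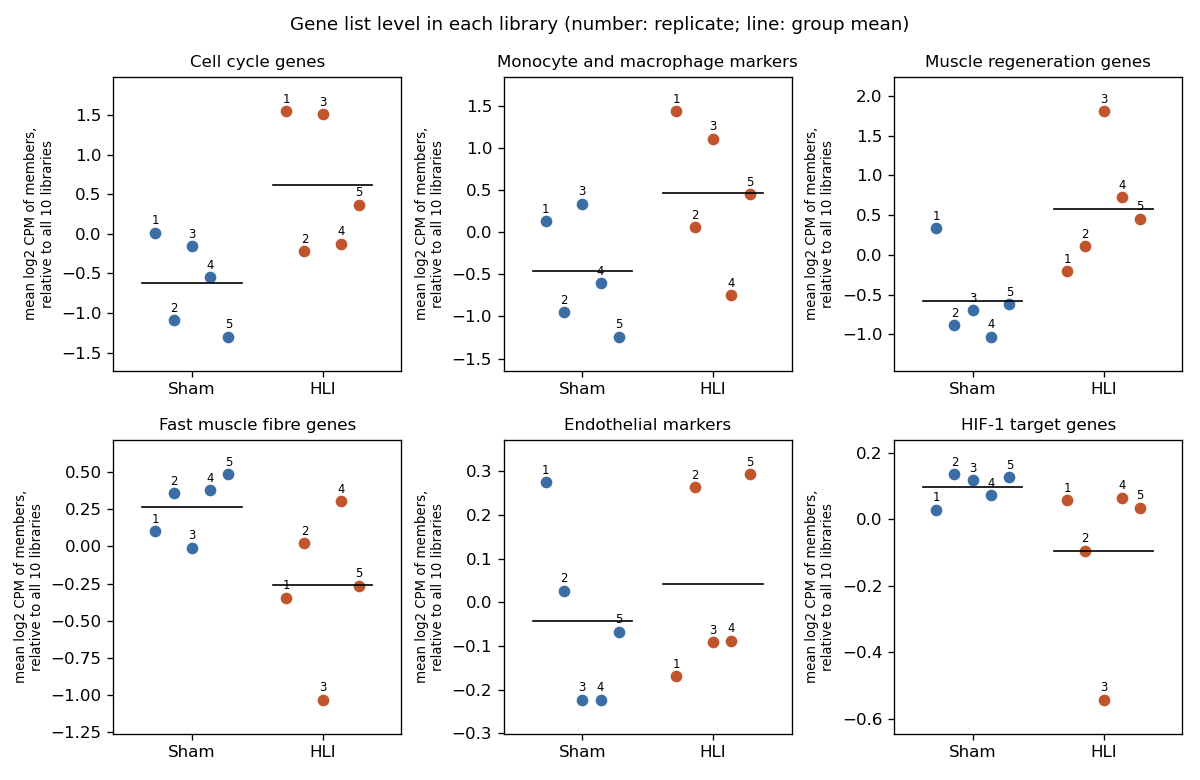
Mean log2 CPM of the members of 6 gene lists in each library, relative to the mean of all 10 libraries; each point is a library marked with its replicate number and the line is the group mean. HLI replicate 3 has the highest regeneration score, 1.81, and the lowest fast fibre score, -1.03, while Sham replicate 1 has a regeneration score of 0.33 against -1.03 to -0.62 in the other Sham libraries.

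Several other groups were called by camera but depended on single libraries. The 19 genes of extracellular matrix and remodelling had a mean log2 difference of 0.56 (SE 0.36, camera adjusted p = 0.0050, and adjusted p = 0.55 with an estimated correlation), and the adjusted p was 0.095 without HLI replicate 1. The mean was 0.35 without HLI replicate 3. Postn, a matrix protein gene of activated fibroblasts, had 247 ± 187 CPM in Sham and 1342 ± 1777 CPM in HLI, with 4520 CPM in HLI replicate 3. Col3a1, which encodes type III collagen, had 2509 ± 999 and 5190 ± 2397 CPM. The 6 erythroid genes had a mean of 0.76 (SE 0.51, camera adjusted p = 0.024, and adjusted p = 0.55 with an estimated correlation). Without HLI replicate 1 the mean was 0.40 and the adjusted p 0.15; in that library Hba-a2, an α-globin gene with a near-identical copy, stood at 686 CPM. The adjusted p was 0.051 without Sham replicate 1. The 9 adipocyte markers had a mean of -0.68 (SE 0.53, camera adjusted p = 0.026, and adjusted p = 0.55 with an estimated correlation). Their score was -2.09 in HLI replicate 4, without which the mean was -0.26 and the adjusted p 0.39, and the adjusted p was 0.068 without Sham replicate 4. The 9 immediate early genes had a mean of 0.34 (SE 0.16, camera adjusted p = 0.037, and adjusted p = 0.51 with an estimated correlation). Their adjusted p was 0.065 without Sham replicate 1, 0.14 without Sham replicate 4, 0.095 without HLI replicate 1, and 0.10 without HLI replicate 3 or HLI replicate 4. Fosb, an immediate early transcription factor gene, had 10.4 ± 4.47 CPM in Sham and 34.6 ± 34.9 CPM in HLI, with 93.5 CPM in HLI replicate 5.

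Across all genes, edgeR called 0 genes higher and 0 genes lower in HLI at an adjusted p under 0.05, with a smallest adjusted p of 0.29. At an unadjusted p under 0.05 it gave 1438 genes higher and 824 lower, 2262 in all where chance alone gives 670 on average. Of 100 splits of the samples into 5 and 5, the real one included, 5 gave at least 2262, so chance could not be excluded. DESeq2 called 38 genes higher and 7 lower, among them the cell cycle genes Cdk1, Cenpf, Plk1, Top2a and Mki67, and gave 2767 genes at an unadjusted p under 0.05. The DESeq2 adjusted p of Top2a and Mki67 was 0.05 after rounding. DESeq2 was run without the filter on low counts, and the TPM fits used a filter on TPM, so these counts are not over the same genes. On unscaled TPM, limma gave 2121 genes higher and 259 lower at an unadjusted p under 0.05, and on quantile-normalized TPM 883 higher and 1074 lower. The unscaled TPM moved the median log2 fold change of all genes by 0.16, from 0.03 to 0.19. Ranges of the groups did not overlap for 221 genes, 104 higher and 117 lower, where chance gives 0.79% of genes or 106 on average. How far this count varies over other splits of the samples was not examined. Because no gene passed the test, the genes named here other than the 9 fixed before the data were examined were chosen after their values were seen. Most were taken from the smallest unadjusted p-values, Myh3, Myh8 and Myl4 were singled out apart from that rule, and the values of all of them are descriptions.

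Among the genes with the smallest unadjusted p-values, Ugcg, which encodes glucosylceramide synthase, had 18.1 ± 4.29 CPM in Sham and 34.6 ± 9.03 CPM in HLI (SD, n = 5), a log2 fold change of 0.93 (SE 0.20). Clec12a, a myeloid lectin receptor gene, had 7.69 ± 3.24 and 21.0 ± 10.3 CPM, Tmsb10, an actin-binding thymosin gene, had 26.5 ± 5.77 and 48.0 ± 14.99 CPM, and Trim25, a ubiquitin ligase gene of antiviral signalling, had 35.6 ± 2.75 and 51.3 ± 7.79 CPM. On the lower side, Mss51, which encodes a mitochondrial protein of muscle, had 51.8 ± 14.3 CPM in Sham and 22.5 ± 6.64 CPM in HLI. Its log2 fold change was -1.20 (SE 0.24). Otub2, a deubiquitinase gene, had 15.5 ± 4.003 and 7.98 ± 1.16 CPM, Tmem140 had 35.9 ± 4.09 and 26.6 ± 1.64 CPM, and Cpeb1, an mRNA-binding protein gene, had 37.4 ± 3.47 and 21.9 ± 6.70 CPM. Med25, a subunit gene of the Mediator complex, had 55.4 ± 4.34 and 41.1 ± 4.53 CPM. The edgeR adjusted p of these 9 genes was 0.29, and that of DESeq2 lay between 0.014 and 0.050. For Mss51 and Otub2, Sham replicate 1 was the lowest Sham library, at 28.1 and 9.25 CPM.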

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

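All tests in this part were chosen after the results were seen. A library stood far from the other 4 of its group in 18 of the 188 groups of values examined, by Dixon's ratio, where chance gives about 9.4 if no group is picked by its values. Most of the genes were picked after their values were seen, Myh3, Myh8 and Myl4 among them, so this count is not a test. In the 80 groups of list scores, fixed genes and library measures, which were not picked in this way, a library stood apart in 3, where chance gives about 4.

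Several of these values lay in Sham replicate 1. Myh3 stood at 164 CPM there against 3.97 to 5.63 CPM in the other Sham libraries, Myh8 at 78.2 CPM against 1.43 to 3.11 CPM, and Myl4, an embryonic myosin light chain gene, at 28.3 CPM against 4.39 to 7.09 CPM. Col3a1 stood at 4291 CPM against 1985 to 2185 CPM, and Mfap5, a matrix gene of fibroblasts, at 134 CPM against 64.8 to 69.3 CPM. Cldn5, an endothelial junction gene, stood at 50.0 CPM against 27.9 to 32.8 CPM, and Mss51 at 28.1 CPM against 52.9 to 66.4 CPM. An exchange with HLI replicate 2, 3 or 5 would leave the pattern in place, as the lowest of them held 80 CPM of Myh3, Myh8 and Myl4 also lay over 2-fold above Sham replicates 2 to 5, and each was closest to another HLI library once Sham replicate 1 was set aside, which argues against it. An exchange with HLI replicate 4 stays open. That library held 165 CPM of Myh3, so the pattern would remain, but it was closest to Sham replicate 4. This exchange gave 2318 called genes against 0. The number does not bear on a label error, since that grouping also parts the libraries along their main axis of variation. An exchange with HLI replicate 1 stays open: that library had 7.71 CPM of Myh3, 1.65 of Myh8 and 4.41 of Myl4, near the other Sham libraries, but a cell cycle score of 1.55 and a macrophage score of 1.44, above them, and was closest to HLI replicate 5. A wrong label of this library alone, or an exchange with a sample outside the series, stays open too. Its closest library was HLI replicate 5 (r = 0.985 across genes, against 0.976 with its closest Sham library), and it was itself the closest library of HLI replicates 2 and 5, which go with such a wrong label. With it left out, HLI replicate 4 was still closest to a Sham library (r = 0.970 with Sham replicate 4), so a closest library in the other group is not enough to decide. Regeneration in the muscle labelled Sham stays open too, and no biological explanation was tested.

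In HLI replicate 3, Postn stood at 4520 CPM against 452 to 644 CPM in the other HLI libraries, Myl3 at 38.5 CPM against 265 to 344 CPM, and the HIF-1 target score at -0.54 against -0.09 to 0.07. In HLI replicate 1 the stress score was 0.77 against -0.39 to -0.06, and Apln stood at 13.8 CPM against 25.1 to 29.8 CPM. The stress score of Sham replicate 3, at 0.72, was close to that of HLI replicate 1. HLI replicate 4 had 37.5 CPM of Trim25 against 53.0 to 55.8 CPM, and 79.4 CPM of Mfap5 against 118 to 138 CPM. Sham replicate 3 had 93.02 CPM of the β-globin gene Hbb-bt against 40.4 to 46.9 CPM, and 280 CPM of Hba-a2 against 126 to 156 CPM. Sham replicate 2 had 16.3 CPM of Vhl against 13.0 to 13.7 CPM, and 30.9 CPM of Trim25 against 35.9 to 38.0 CPM.

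Macrophage, lymphocyte and cell cycle lists were higher and muscle fibre lists lower in HLI by camera with a preset correlation. With an estimated correlation 0 lists passed. Neutrophil markers were not called, with a mean of 0.12 (camera adjusted p = 0.94). A lower share of muscle fibre RNA alone would raise markers of every other cell type alike. The mean change of macrophage, neutrophil and lymphocyte lists was 0.78 on the log2 scale and that of endothelial, pericyte, fibro-adipogenic, adipocyte and Schwann cell lists -0.13, a difference of 0.91 (SE 0.47, n = 5 and 5, exact two-sided permutation p = 0.0873), so this explanation stays open. The difference lay between 0.67 and 1.16 when each library was left out. Which lists are compared with the resident ones decides the outcome: p was 0.0873 with erythroid genes added, 0.0317 with macrophage and lymphocyte lists, 0.0397 with the cell cycle list and 0.0238 with macrophage, lymphocyte and cell cycle lists, the last chosen because they were seen to be higher. The variance of the changes over 9 lists of cells other than fibres had a permutation p of 0.127. The scaling factors alone are argued against, since on unscaled TPM all 4 of the fast fibre, slow fibre, macrophage and cell cycle lists kept their direction, with differences of -0.32, -0.32, 1.11 and 1.10. Immune cells or dividing cells added with HLI remain an untested hypothesis, and differences between samples unrelated to HLI stay open, as the splits show.

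Chance could not be excluded for the numbers of genes at an unadjusted p and of lists, from 100 of the 126 splits of the 10 samples into 5 and 5, the real split included in each count. For genes at an unadjusted p under 0.05, 5 of 100 splits gave at least 2262, the value of the real one, with 4907 as the highest other; a share of 0.05 lies just at the limit. For lists called by camera with a preset correlation, 11 of 100 splits gave at least 17, with 19 as the highest other, and the median of the other splits was 12 lists. For genes called by edgeR the real split gave 0, which all 100 of 100 splits must reach, so this count tests nothing. The split with the highest number, 2318 genes called, differs from the real one by an exchange of Sham replicate 1 and HLI replicate 4, and that with 112 by an exchange of Sham replicate 1 and HLI replicate 1. The 2318 genes came from a grouping that follows the first principal component, the main axis of variation, which held 43.6% of the variance. Sham replicate 1 and HLI replicates 1, 2, 3 and 5 lay below 0 on it, and the other libraries above. A grouping along that axis can give many calls whatever the labels, so the count of 2318 is not evidence on a label error. The sides of this axis follow the labels for all libraries but Sham replicate 1, at -4.89, and HLI replicate 4, at 14.4. Sham replicate 3 lay near 0, at 1.96, and no comparison was made on this axis.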

How the results depend on the processing

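The TPM fits, fry and the permutation of list scores were chosen after seeing the data. edgeR, and limma on TPM, called 0 genes under each alternative, the fold-change threshold included, and DESeq2 called 38 higher and 7 lower. The smallest edgeR adjusted p, 0.29 with all libraries, was 0.062 without Sham replicate 1 and 0.077 without HLI replicate 4. It lay between 0.25 and 0.57 when any other library was left out. The simulated data gave calls at this number of samples and depth, but with genes drawn independently. In the real data the estimated inter-gene correlation was 0.84 for cell cycle genes and 0.86 for fast fibre genes. The simulation therefore does not check the 0 calls, or the preset correlation, on libraries like these. Genes higher at an unadjusted p under 0.05 ranged from 693 (without HLI replicate 3) to 2227 (without HLI replicate 4), and genes lower from 372 (without Sham replicate 5) to 1954 (without HLI replicate 4), against 1438 and 824. TPM gave 259 lower, or 261 with a pseudocount of 0.1, and quantile-normalized TPM 883 higher. The Fgf13 log2 fold change ran from -0.44 to -0.0036 and passed under no alternative.

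Lists called were 17, from 14 to 18 when a library was left out, and 0 with an estimated correlation, with fry (smallest adjusted p = 0.24) and with the exact permutation test (7 at an unadjusted p under 0.05, smallest adjusted p = 0.17). Of 364 list values, 308 kept direction and side of the threshold, 9 newly passed, 39 no longer passed and 8 reversed. Of 1184 values of 63 named genes, 1167 were kept, 11 newly passed, all with DESeq2, and 6 reversed. These genes did not pass in the main fit, and most were picked for a small p. The share kept was therefore largely set by that choice and does not measure stability.

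Over the list alone, cell cycle genes passing ranged from 7 to 17 without each library and were 9 on quantile-normalized TPM, against 16. Regeneration genes ranged from 0 to 7 and were 0 on quantile-normalized TPM, against 6. Lymphocyte markers ranged from 0 to 9, were 0 with TPM and quantile-normalized TPM and 3 with a pseudocount of 0.1 and with median of ratios, against 5. Cytokines ranged from 0 to 4, against 3.

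Values that reversed in these fits were Vegfa on TPM (0.00042) and Kdr on TPM (0.12, and 0.12 with a pseudocount of 0.1), where the median of all genes was 0.19 and 0.21 and lay above both genes; on TPM scaled by median of ratios they were -0.20 and -0.08. Others were Kdr without single libraries (-0.20 to 0.046), the FGF family without the filter (0.019), and neutrophil markers with quantile normalization (-0.066) and without single libraries (-0.41 to 0.62). Without single libraries Schwann cell markers ranged from -0.31 to 0.078 and stress genes from -0.33 to 0.032. On unscaled TPM, not among these list values, means lay above 0 for HIF-1 targets (0.0023), HIF subunits and turnover (0.12), the FGF family (0.085), pericyte markers (0.14), atrophy (0.057), Schwann cell markers (0.015) and stress genes (0.027), but relative to the median of all genes there all 7 lay below 0 (-0.18 to -0.05), so the shift of all genes accounts for these signs. The cause was not tested for the other changes, except that leaving out a library leaves fewer samples.

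Replicate numbers were not taken to pair the samples, since not every pair correlated: deviations of same-numbered libraries correlated at 0.00012, 0.18, 0.28, 0.19 and -0.0090, and 2 of 5 libraries matched best with their own number. With the number as a block edgeR called 0 genes (smallest adjusted p = 0.092), 1712 genes were higher and 1274 lower at an unadjusted p under 0.05, Hif1a had a log2 fold change of 0.53 (adjusted p = 0.13), 15 lists were called and 0 lymphocyte markers passed over the list alone. The planned FPKM fits were not run, as the table holds TPM.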

Other observations

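The correlations of Fgf13 and the differences on unscaled TPM in this part were chosen after the results were seen; the list tests were planned. Further gene lists did not pass the camera test with all libraries. The 17 genes of oxidative, heat and unfolded-protein stress had a mean log2 difference of -0.12 (SE 0.28, camera adjusted p = 0.062, and adjusted p = 0.57 with an estimated correlation), and 0.03 on unscaled TPM, or -0.16 relative to the median of all genes. Within this list Atf4, a transcription factor gene of the integrated stress response, had 184 ± 31.2 CPM in Sham and 121 ± 29.4 CPM in HLI, and its target gene Ddit3 had 13.1 ± 2.69 and 9.31 ± 1.74 CPM. The list's adjusted p was 0.0011 without HLI replicate 1, 0.028 without Sham replicate 4 and 0.020 without Sham replicate 5, 0.042 without the filter on low counts, and its mean was -0.33 without HLI replicate 1 and 0.03 without Sham replicate 3. The 16 genes of muscle atrophy and proteolysis had a mean of -0.13 (SE 0.12, camera adjusted p = 0.16), and 0.06 on unscaled TPM, or -0.13 relative to the median of all genes. It was -0.075 without Sham replicate 3 and -0.22 without HLI replicate 4. Cdkn1a, a cell cycle inhibitor gene, had 24.8 ± 5.99 and 40.5 ± 17.0 CPM, and Sqstm1, an autophagy receptor gene, 631 ± 117 and 425 ± 132 CPM. The 12 fibro-adipogenic progenitor markers had a mean of 0.11 (SE 0.15, camera adjusted p = 0.53), 0.05 without Sham replicate 3 or HLI replicate 2 or 5, 0.18 without Sham replicate 1, 0.21 without HLI replicate 4 and 0.21 after quantile normalization. The 10 Schwann cell and nerve markers had a mean of -0.12 (SE 0.35, camera adjusted p = 0.44), 0.02 on unscaled TPM, or -0.17 relative to the median of all genes, -0.31 without Sham replicate 1, 0.08 without Sham replicate 5 and 0.05 without HLI replicate 3.

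The spread between samples was larger in HLI than in Sham for 71.9% of the 13404 genes. The first principal component held 43.6% of the variance, and HLI replicate 3 lay at one end of it at -69.9 and Sham replicate 5 at the other at 46.5.

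Fgf13 differed between libraries within both groups, and the hypothesis was tested that it follows the share of muscle fibre RNA. Over the 10 libraries Fgf13 correlated with the fast fibre score (Pearson r = 0.863, permutation p = 0.00097, and Spearman rho = 0.891, permutation p = 0.0012; adjusted over 5 lists 0.0029 and 0.0031), with r = 0.806 without HLI replicate 3 and Sham replicate 5 and r = 0.852 after removing group means. It correlated with the slow fibre score at r = 0.838 (permutation p = 0.0012, adjusted 0.0029; rho = 0.927, permutation p = 0.00032, adjusted 0.0016). With the endothelial score r was -0.254 (permutation p = 0.478, adjusted 0.60; rho = -0.212, permutation p = 0.561, adjusted 0.70), so whether Fgf13 also follows the endothelial share stays open. Among all genes, Fgf13 lay at the 90.0 percentile of r with the fast fibre score, so the relation is not special to Fgf13. Muscle fibres may therefore be a source of the Fgf13 signal in whole muscle, a hypothesis found and tested on the same libraries; the other 2 relations, with pericyte and Schwann cell lists, had r of -0.09 and 0.40 (adjusted permutation p = 0.81 and 0.43; rho = -0.13 and 0.37, adjusted permutation p = 0.73 and 0.49).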
